A study of Mus musculus with 6 samples.

How the data were processed

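Guts were dissected from mouse embryos at stage E10.5, and polyadenylated RNA was made into Illumina TruSeq libraries, per the labels' protocols. The series names an Illumina HiSeq instrument and paired reads of 75 bp. The labels give 3 wildtype and 3 Ret null samples, and genotype was the grouping used. They do not say whether each sample was 1 embryo or several. Picard, TopHat2, Cufflinks and Cuffdiff and the build mm10 are named in the submitters' processing notes, without versions, and their settings and the gene annotation are not given in the sources used here.

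The analysis rests on 1 table in the layout of Cuffdiff's gene test, with 1 line per gene. Its 2 value columns hold an FPKM value per genotype, made by the authors from the libraries of that genotype and printed here as the authors' values without a spread or n. The deposited columns name the genotypes by a letter each, read here as wildtype and homozygous null, which the value of Ret goes with. The p-value and q-value columns, the log2 fold change and the test statistic, a score in units of its own standard error, are the authors' own results per the file headers. Of 23234 lines, 1 had 2 records run together and was not used, leaving 23233. The authors' status column marks 13430 as tested, 9802 as not tested and 1 as holding too many reads. The deposited log2 column holds a spreadsheet error text in 590 cells and 26 symbols had been turned into dates, so log2 fold changes were recomputed from the FPKM values. They differed from the deposited ones by at most 0.12. Symbols were repeated on 254 lines and 193 lines carry several merged symbols. Of 23040 single symbols, 21253 were found in the RefSeq gene table of GRCm38.p6, the same build as mm10. The file's starts count from 0 and were raised by 1, and 35.5% of the matched lines then had exactly the reference start and end. Other lines can span several overlapping genes, so coordinates are printed only for exact matches.

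The design fixed before the data were examined foresaw a table with 1 value per genotype, and for it took the authors' deposited q under 0.05 as the test, with the direction of the log2 fold change. With no value per sample, no test of replicates could be run, and the n of 3 per genotype enters only through the authors' statistic. Nothing in the labels says that the samples came from separate litters. The deposited q-values equal a Benjamini-Hochberg adjustment of the deposited p-values over the tested lines to within 5.9e-05. The smallest p-value in the authors' deposited table is 5e-05, held by 867 genes. The implied standard error of each gene was its log2 fold change divided by the authors' test statistic. Its median was 0.61 for genes under 1 FPKM, 0.39 from 1 to 5 FPKM, 0.22 from 5 to 20 FPKM and 0.17 over 100 FPKM, so changes of genes with low values are the least certain. The smallest change called was 0.34 on the log2 scale from 1 to 5 FPKM and 0.28 over 100 FPKM. No counts are in the table, so depth is unknown and no counting intervals are given. A value listed at 0 was given no fold change. The median log2 fold change of expressed genes was 0.01, and no further normalization was applied.

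Gene lists (43) were fixed before the data were examined and cover Ret signalling, crest, neuronal and glial genes, gut and neighbouring tissues, blood, pathways, cell state and sex. The list of mitochondrially encoded genes matched no line, leaving 42. Of 905 listed lines, 70 are in more than 1 list. For each list the called genes were counted, called and uncalled genes inside and outside it were compared by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over 42 lists, and calls were also adjusted over the list alone. The median log2 fold change with 1 FPKM added was placed among 10000 random lists matched on mean expression in 20 bins, as a description of these values only. Genes are not independent replicates, so these tests describe the table and not variation between embryos. Fisher's tests were not matched on expression, and the share of tested genes called was 34.7% under 1 FPKM and 6.43% over 100 FPKM. Calls within 10 Mb of Ret and per chromosome were compared in the same way.

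Named genes followed a rule fixed beforehand: Ret, the 12 largest falls and 12 largest rises among called genes at 1 FPKM or more and above 0 in both genotypes, up to 4 called members per list by smallest q and then largest change (with no call, the 2 members with the highest mean), and the members at 1 FPKM or more of the lists for the Ret receptor, the Ret regulators and endothelin signalling. Some genes that the rule takes are not reported here. Genes outside it are said to be named or chosen after their values were seen. Genes with near-identical copies, such as Gm5506 and the zinc finger gene Zfp534, can share reads with them and are uncertain.

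Alternatives fixed beforehand were q thresholds of 0.01 and 0.1, minimum values of 1 and 5 FPKM, a 1.5-fold minimum, adjustment over expressed genes alone, centring, added values of 0.1 and 1 FPKM, and windows of 5 and 20 Mb. A p from the test statistic and counts without X and Y genes were added after the data were seen. The functions were tested on simulated log2 fold changes for 13422 genes with the real implied standard errors and 200 changed genes: 66.7% of changes of 1 and 88.8% of changes of 2 on the log2 scale were recovered for Ret null against wildtype, and 4.91% of calls were false. The simulated genes were called by p as a normal deviate. These rates therefore do not describe the power or error of calls by the authors' q. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.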

Results

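The series measured messenger RNA in whole guts dissected from mouse embryos at stage E10.5, when neural crest cells are colonising the gut to form its nervous system. The comparison was between 3 wildtype gut samples and 3 samples homozygous for a null allele of Ret, the receptor tyrosine kinase through which GDNF family ligands act on these cells. All 6 samples carry the strain label C57BL/6J, and the series describes the embryos as male. The deposited table gives 1 FPKM value (fragments mapped to a gene, scaled to transcript length and library size) per genotype and no value per sample, so no spread between replicates can be shown, and read depth is unknown. Of 23233 gene lines, 13430 had been tested by the authors and 13321 of these reached 1 FPKM or more in at least 1 genotype. Errors after ± are the standard errors of the log2 fold change implied by the authors' test statistic. The authors' q-values do not follow from these errors. All fold changes are Ret null relative to wildtype, and genes are said to rise, fall or change only where q was under 0.05 in the authors' deposited table. The smallest q in the authors' deposited table was 0.000775, which all genes described below as changed had unless another q is given.

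Ret itself was nearly lost from the Ret null value. It stood at 8.80 FPKM in wildtype and 0.0354 FPKM in Ret null gut, 249-fold lower, with a log2 fold change of -7.96 ± 1.18 and q = 0.0042 in the authors' deposited table. The line spans the whole annotated gene on chromosome 6, 118151748 to 118197744 (mm10). It was the largest fall of any called gene at 1 FPKM or more and above 0 in both genotypes. The labels do not say which part of the gene the null allele lacks. With 1 FPKM added to both genotypes the log2 fold change was -3.24.

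The transcriptome changed broadly. The authors' test called 1956 genes, of which 1192 fell and 764 rose in Ret null gut. The falls include 3 genes listed at 0 in Ret null gut (Hfe2, Myoz2 and 1110059M19Rik, named after their values were seen). At 1 FPKM or more, 339 genes fell and 254 rose at least 2-fold, and 86 fell and 62 rose at least 4-fold. The largest falls after Ret were in Uncx, a somite transcription factor (30.7-fold), Chrng, a subunit of the muscle acetylcholine receptor (23.5-fold), and the muscle genes Tnnc2 (21.5-fold), Myh3 (20.4-fold) and Myl1 (19.7-fold). Tbx15 (from 1.28 to 0.0670 FPKM), Cst9 (17.9-fold), Myog (15.9-fold) and Arpp21 (14.7-fold) were also among the 12 largest falls. In the authors' deposited table q was 0.0042 for Uncx, 0.0211 for Chrng, 0.00372 for Tnnc2 and 0.00566 for Tbx15. The largest rises were in Xist (235-fold), the long noncoding RNA that silences an X chromosome in female cells, and in Alb (168-fold), the albumin gene of hepatocytes. Next came Cym, which encodes the stomach protease chymosin (64.0-fold), Gm5506 (35.1-fold), Afp, encoding alpha-fetoprotein (31.7-fold), Itih2 (29.2-fold) and Barx1, a homeobox gene of stomach mesenchyme (24.5-fold). Kng1, F2, Nepn, Zfp534 and Apoa2 completed the 12 largest. Folds that rest on a value near 0 are the least certain. Kng1 went from 0.0474 to 1.16 FPKM (4.61 ± 2.74 on the log2 scale) and did not pass q under 0.01 in the authors' deposited table. With 1 FPKM added to both genotypes the log2 fold changes of Kng1, F2 and Zfp534 were 1.04, 1.65 and 1.30. Among the falls Arpp21 also had a wide error (-3.88 ± 1.73). In the authors' deposited table q was 0.0222 for Cym, 0.0153 for Kng1, 0.00924 for F2 and 0.00263 for Zfp534. The count depends on how p was obtained: p computed from the authors' test statistic as a normal deviate, an alternative added after the data were seen, gave 607 genes. A minimum change of 1.5-fold left 1158 genes.

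**Figure D1:**
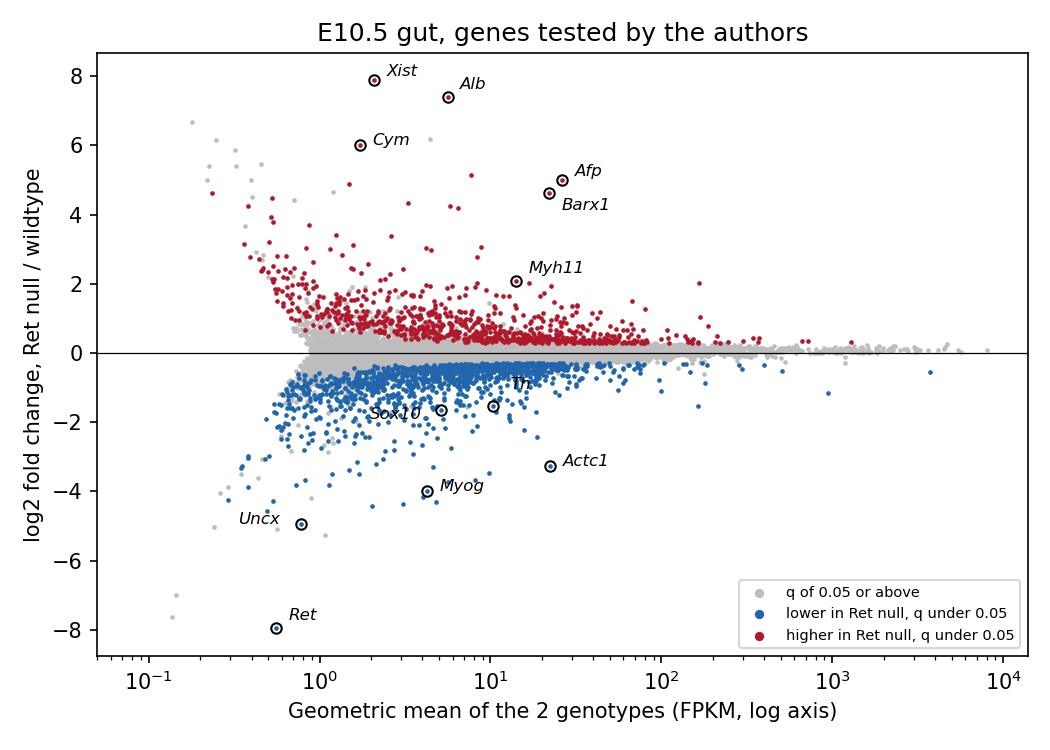
Each point is a tested gene with a value above 0 in both genotypes, with the geometric mean of its wildtype and Ret null FPKM on the log x axis and its log2 fold change (Ret null over wildtype) on the y axis; blue and red points passed q under 0.05 as lower and higher. Ret lies at -7.96, and Xist, Alb and Afp lie at 7.88, 7.39 and 4.99.

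Among Ret's own receptor complex and ligands, 3 of 10 tested members fell, 2 rose and 5 did not pass (adjusted Fisher's exact p = 0.0152). Besides Ret, the co-receptor Gfra3 fell 1.95-fold and Sorl1 fell 1.38-fold, with q = 0.00206 and q = 0.0137 in the authors' deposited table. The ligand Gdnf rose from 8.73 to 14.9 FPKM (log2 fold change 0.77 ± 0.20) and the co-receptor Gfra1 from 14.9 to 28.1 FPKM (0.92 ± 0.19). Gfra2, Ncam1, Gfra4, Nrtn and Artn had log2 fold changes of -0.30, -0.18, 0.02, 0.20 and 0.22. Of 24 tested adaptors and effectors of Ret, 1 fell and 3 rose (adjusted Fisher's exact p = 0.809). Cbl, a ubiquitin ligase acting on receptor tyrosine kinases, fell 4.23-fold, and Cblc, Grb7 and Pdlim7 rose by log2 fold changes of 1.85, 1.11 and 0.45, with q = 0.0175 for Cblc and q = 0.00372 for Pdlim7 in the authors' deposited table. Among 10 tested transcriptional regulators of Ret, 4 fell and 2 rose (adjusted Fisher's exact p = 0.00246). Among the falls, Sox10 went from 9.15 to 2.89 FPKM and Gata2 from 15.6 to 10.1 FPKM. Nkx2-5 rose 4.42-fold and Hand2 rose by a log2 fold change of 0.30 (q = 0.0296 in the authors' deposited table), while Phox2a, Etv5, Rarb and Hoxb5 had log2 fold changes of -0.76, -0.17, 0.19 and 0.24 and did not pass. In endothelin signalling, which acts beside Ret in enteric crest cells, 1 of 6 tested members fell and 1 rose (adjusted Fisher's exact p = 0.263). Ednra had a log2 fold change of -0.31 and Ece1 of 0.37, with q = 0.0338 and q = 0.00613 in the authors' deposited table. The crest receptor Ednrb stood at 18.8 FPKM in wildtype and 17.5 in Ret null (-0.10 ± 0.19), and its ligand Edn3 at 15.5 and 16.9 FPKM, and neither passed. With p from the test statistic as a normal deviate (the normal p), 1 receptor and ligand member was lower and 2 higher, 1 adaptor lower and 1 higher, and 3 regulators lower and 1 higher, and no endothelin member passed.

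Genes of neural crest progenitors, neurons and glia were mostly lower in Ret null gut. Of 28 tested enteric neural crest progenitor markers 19 fell and 3 rose, with a median log2 fold change of -0.67 on the scale with 1 FPKM added. Sox10 (-1.66 ± 0.30) and Tfap2b (-1.65 ± 0.39) were among the largest falls, and the risers were Gfra1, Hand2 and Snai2, the last named after its value was seen (q = 0.0109 in the authors' deposited table). Sox10 lies on chromosome 15, 79154913 to 79164490. Of 34 tested neuronal differentiation markers 27 fell and 2 rose (median -0.71), the risers being Isl1 and Crmp1, of which Crmp1 was named after its value was seen. The nicotinic receptor subunit genes Chrna3 and Chrnb4 fell 6.08-fold and 6.03-fold, the neuropeptide gene Cartpt 5.92-fold, and the neuronal tubulin gene Tubb3 from 23.8 to 6.90 FPKM. Of 13 tested catecholamine and transmitter genes 5 fell and 0 rose (median -0.44). These included Dbh and Th, enzymes of catecholamine synthesis, at 2.98-fold and 2.90-fold lower, and the vesicular transporter Slc18a2 at 2.09-fold lower. Of 11 tested glial and Schwann lineage markers 7 fell and 1 rose (median -0.46). Dhh fell 3.38-fold and Ngfr 2.49-fold, and the riser was Sox2, which endoderm also expresses (3.84-fold). Of 8 tested sensory ganglion markers, which mark crest and placode neurons outside the gut, 3 fell and 1 rose (median -0.31), with Ntrk2 and Ntrk3 at -1.08 and -0.71 and Isl2 at 1.30. Called genes were more frequent in these lists than among other tested genes: by Fisher's exact test (two-sided, adjusted over 42 lists) p = 7.66e-13 for progenitors, 2.52e-18 for neurons, 0.044 for transmitters, 7.05e-05 for glia and 0.0311 for sensory ganglia. Adjusted over the list alone, 19 progenitor, 27 neuronal, 5 transmitter, 7 glial and 4 sensory ganglion members were lower. The medians of the progenitor, neuronal and glial lists lay at percentile 0 of 10000 random lists matched on expression, and those of the transmitter and sensory ganglion lists at 0.01 and 2.39. With p from the test statistic as a normal deviate 12 progenitor, 15 neuronal, 5 transmitter, 4 glial and 1 sensory ganglion members were lower. Alongside these genes, 8 of 10 somite and skeletal muscle markers were lower and 16 of 21 hepatic markers higher in the same Ret null value.

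Among genes implicated in Hirschsprung disease, the absence of enteric ganglia, 10 of 26 tested members fell and 4 rose (Fisher's exact adjusted p = 1.66e-05, two-sided). The falls included Ret, Cbl and Sox10, and the largest rise was in Ihh (3.89-fold). The list's median was 0.03, opposite in sign to the larger number of falls, and with the normal p 6 members were lower and 3 higher. Of 28 tested semaphorin, netrin, slit and ephrin guidance genes 7 fell and 3 rose (adjusted Fisher's exact p = 0.00818). Epha3, Plxna4 and Unc5c had log2 fold changes of -1.80, -1.26 and -0.62, and Efnb2 rose by 0.56. With the normal p 3 guidance members were lower and 1 higher.

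Genes of gut mesenchyme and smooth muscle were mostly higher. Of 24 tested members 17 rose and 2 fell, with a median log2 fold change of 0.72 and an adjusted Fisher's exact p of 2.51e-11. The falls included Des, named after its value was seen (q = 0.00206 in the authors' deposited table). Barx1 rose from 4.46 to 109 FPKM (4.61 ± 0.29) on chromosome 13, 48663036 to 48666507. The smooth muscle genes Actg2 and Mylk rose 2.83-fold and 2.76-fold, and Myh11 rose from 6.93 to 29.1 FPKM. Of 27 tested gut epithelium and endoderm markers 23 rose and 0 fell (median 0.89, adjusted Fisher's exact p = 1.04e-14), among them Foxa2 (5.37-fold), Ihh (3.89-fold), Sox2 (3.84-fold) and Foxa1 (3.71-fold). The medians of both lists lay at percentile 100 of their random lists. In the hedgehog pathway, through which endoderm signals to mesenchyme, 6 of 14 tested members rose and 3 fell (adjusted Fisher's exact p = 8.68e-05). Shh rose from 8.60 to 22.5 FPKM and Foxf1 from 51.3 to 124 FPKM, and Dhh fell. With the normal p 14 mesenchymal, 20 epithelial and 6 hedgehog members were higher, and 0 mesenchymal, 0 epithelial and 1 hedgehog members were lower.

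Markers of organs next to the gut moved in both directions. Of 21 tested hepatic markers 16 rose and 0 fell (median 1.63, adjusted Fisher's exact p = 2.67e-09), with Alb rising from 0.433 to 72.8 FPKM and Afp from 4.68 to 148 FPKM. Of 10 tested pancreatic markers 6 rose and 1 fell (adjusted Fisher's exact p = 0.000289). Nkx6-1 rose 5.50-fold and Gcg, encoding glucagon, 2.55-fold. Of 10 tested somite and skeletal muscle markers 8 fell and 0 rose (median -1.76, adjusted Fisher's exact p = 2.87e-05), including Myog (15.9-fold), Acta1 (13.2-fold), Pax1 (8.85-fold) and Myod1, from 4.79 to 0.456 FPKM. Of 11 tested cardiac markers 7 fell and 1 (Nkx2-5) rose (median -1.64, adjusted Fisher's exact p = 7.05e-05). The falls in this list included Tnnc1 (12.8-fold), Myl4 (9.92-fold) and Actc1 (9.69-fold), contractile genes that embryonic skeletal muscle also expresses. Of 17 tested nephric and gonadal ridge markers 12 fell and 2 rose (median -0.71, adjusted Fisher's exact p = 4.9e-09), with Calb1 14.1-fold, Pax2 5.38-fold and Emx2 3.57-fold lower, and Osr1 and Six2, named after their values were seen, higher. Of 10 lung and anterior foregut markers 5 fell, led by Irx1 (4.19-fold), and 3 rose (adjusted Fisher's exact p = 2.87e-05). Of 10 mesothelium markers 3 fell and 3 rose (adjusted Fisher's exact p = 0.00246), with Tbx18 and Wt1 at -1.18 and -0.78 and Krt19 and Aldh1a2 at 0.85 and 0.42, and q was 0.00145 for Aldh1a2 in the authors' deposited table. Of 5 tested spinal cord and hindbrain markers 3 rose and 0 fell (adjusted Fisher's exact p = 0.038). These were Mnx1, Nkx6-1 and Nkx6-2, and the first pair are also in the pancreatic list. In the authors' deposited table q was 0.00145 for Mnx1 and 0.0105 for Nkx6-2. Of 12 primordial germ cell markers 4 rose and 0 fell. This was 33.3% against 14.5% of other tested genes, a difference that did not pass (adjusted Fisher's exact p = 0.114), while the list's median of 0.31 lay at percentile 99.99 of its random lists. With the normal p 15 hepatic, 4 pancreatic, 1 cardiac, 2 nephric, 2 lung and foregut, 1 mesothelium, 2 spinal cord and 1 germ cell members were higher, and 1 pancreatic, 8 somite, 7 cardiac, 8 nephric, 2 lung and foregut and 2 mesothelium members were lower. In the lists of these paragraphs with 0 members called in a direction, at most 2 members passed an unadjusted p under 0.05 in that direction and 0 passed with the normal p.

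**Figure D2:**
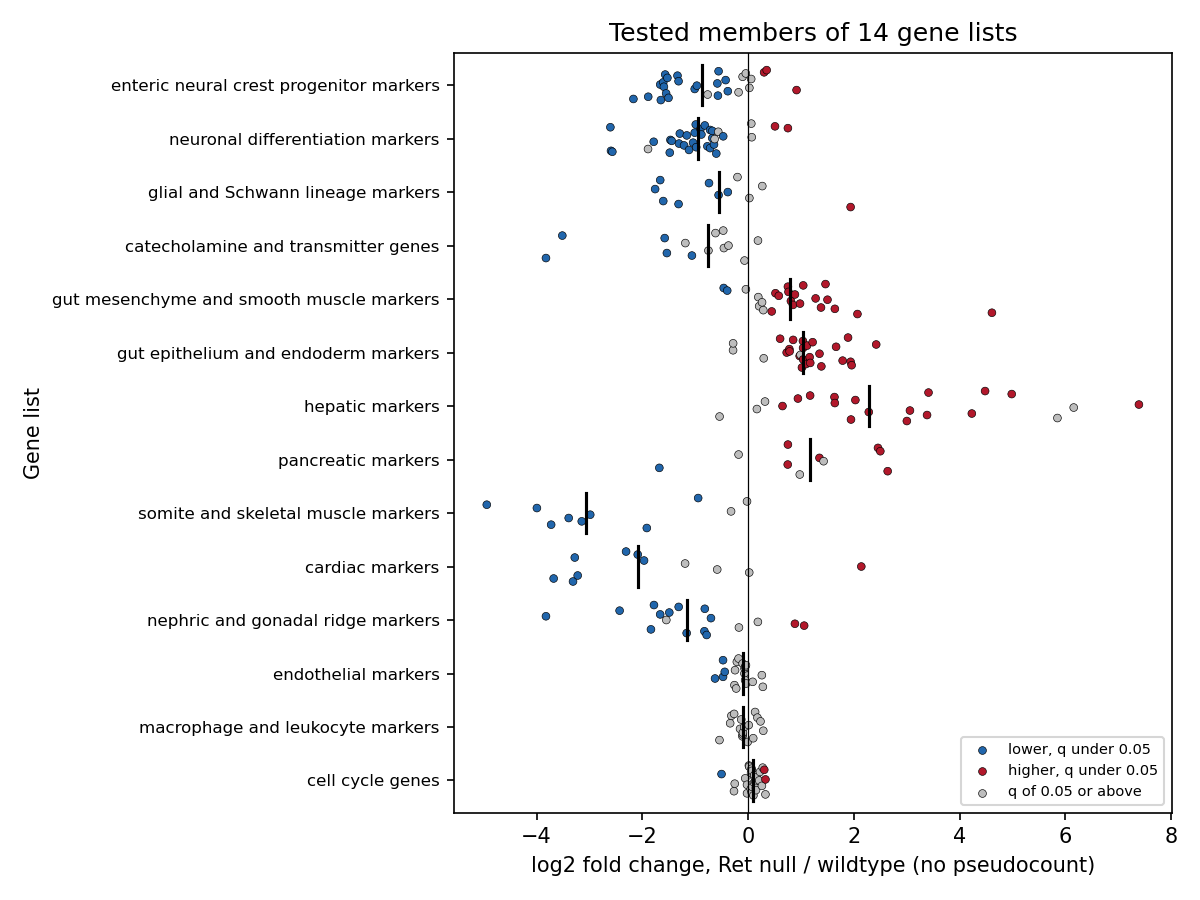
Points are the tested members of 14 gene lists, placed by log2 fold change (Ret null over wildtype, no FPKM added) on the x axis, with lists on the y axis; black bars are list medians and blue and red points passed q under 0.05 as lower and higher. In the hepatic list 16 of 21 members were higher, and in the somite and skeletal muscle list 8 of 10 were lower.

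Hox genes, which are expressed in nested domains along the body axis, held more falls than rises. Of 35 tested members 15 fell and 8 rose (adjusted Fisher's exact p = 6.02e-11), and the median of -0.25 lay at percentile 0 of the random lists. The rises were less stable: 14 members were lower and 4 higher at q under 0.01 in the authors' deposited table, and with the normal p 12 were lower and 1 was higher. Hoxc10, Hoxc9 and Hoxa9 fell 3.27-fold, 2.61-fold and 2.56-fold, and Hoxd13 rose from 2.49 to 5.97 FPKM. In the hindgut and cloaca list 5 of 11 members fell and 3 rose (adjusted Fisher's exact p = 7.05e-05), with Hoxd11 at -0.83 and Cdx2, an intestinal homeobox gene, at 0.98.

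Signalling and matrix lists held calls both ways. In the Wnt pathway 9 of 28 members fell and 3 rose (adjusted Fisher's exact p = 0.000681), with Wnt2, Wnt6 and Dkk1 at -1.66, -1.63 and -1.40 and the secreted antagonist gene Sfrp5 8.21-fold higher. In the retinoic acid pathway 4 of 17 fell and 4 rose (adjusted Fisher's exact p = 0.00283), with Aldh1a3, Crabp1 and Crabp2 lower and Aldh1a2 higher. Of 32 extracellular matrix genes 8 fell and 4 rose (adjusted Fisher's exact p = 0.00246), with Tnc, Postn and Col2a1 at -0.89, -0.88 and -0.79 and Eln at 0.71. In the Notch (3 of 17 fell, 1 rose), BMP and TGF-beta (3 of 23 fell, 4 rose) and FGF and ERK feedback (2 of 19 fell, 3 rose) lists 23.5%, 30.4% and 26.3% of members were called. The differences from other tested genes did not pass (adjusted Fisher's exact p = 0.346, 0.0935 and 0.231), with odds ratios of 1.81, 2.57 and 2.10. Within the last of these lists Dusp6, a feedback phosphatase of ERK signalling, fell by 0.63 on the log2 scale, while Phlda1, Fgf10 and Fgfr2 rose by 0.91, 0.86 and 0.60. The normal p ended most calls in these lists: 4 Wnt, 3 retinoic acid, 4 matrix, 1 BMP and TGF-beta and 1 FGF and ERK members were lower, and 1 Wnt, 1 retinoic acid, 1 matrix and 3 FGF and ERK members higher. No Notch member passed with it.

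Vessel and platelet lists had low medians. Of 19 endothelial markers 4 fell (21.1%, against 14.6% of other tested genes; adjusted Fisher's exact p = 0.562) and 0 rose, led by Emcn at -0.62, and 0 fell with the normal p. At an unadjusted p under 0.05, 6 were lower and 2 higher. The list's median of -0.09 lay at percentile 1.0 of its random lists. No macrophage and leukocyte marker of 17 passed in the authors' Cuffdiff test, at an unadjusted p under 0.05 or with the normal p (adjusted Fisher's exact p = 0.207), and C1qb and C1qc stood at -0.13 and -0.01. Of 8 platelet and megakaryocyte markers 2 fell (25%; Vwf at -0.76, and Plek at -0.57 with q = 0.0268 in the authors' deposited table; adjusted Fisher's exact p = 0.373), and the median of -0.32 lay at percentile 0.71. In the erythroid list 3 of 19 tested members fell and 4 rose (adjusted Fisher's exact p = 0.0234). The embryonic globin genes Hbb-bh1 and Hba-x fell by 1.54 and 1.17 on the log2 scale, and Gata1 rose 3.44-fold. With the normal p 1 platelet and 2 erythroid members were lower and 2 erythroid members higher.

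In proliferation and stress lists the share of calls did not differ from elsewhere past the threshold. In ribosomal and histone lists it was lower than among all other tested genes pooled, without matching on expression. Of 29 cell cycle genes 1 fell (Ccnd1, -0.50) and 2 rose (Plk1, 0.33, and Aurkb, 0.31). Of 22 p53 target and apoptosis genes 1 fell (Trp53inp1, -0.49), of 19 immediate early and dissociation stress genes 2 rose (Myc, 0.53, and Klf4, 0.43), and of 26 hypoxia and glycolysis genes 2 fell and 3 rose (19.2%, against 14.6% of other tested genes). The adjusted Fisher's exact p was 0.81, 0.285, 1 and 0.618 for these lists in order. The median of the stress list (0.15) lay at percentile 99.81 of its random lists. With the normal p no cell cycle, p53 or stress gene passed, and 1 hypoxia and glycolysis gene was higher. In the authors' deposited table q was 0.00206 for Ccnd1, 0.0167 for Plk1, 0.0299 for Aurkb and 0.0341 for Klf4. None of 26 tested histone cluster genes passed in the authors' Cuffdiff test or with the normal p, and 1 had an unadjusted p under 0.05 (adjusted Fisher's exact p = 0.038 for fewer calls than elsewhere). Calls were rarer at high expression, at 6.43% of tested genes over 100 FPKM, and Fisher's tests were not matched on expression. In the ribosomal protein list 2 of 96 fell and 2 rose (4.17%, adjusted Fisher's exact p = 0.00375 for fewer calls). Of these Rplp2 (0.31, q = 0.0281 in the authors' deposited table) encodes a ribosomal protein, and Rps6ka1, Rps6ka2 and Rps6ka3 encode kinases that share the name prefix, with q = 0.0211 for Rps6ka1 and q = 0.0422 for Rps6ka2 in the authors' deposited table. Over the 42 lists, counts adjusted over the list alone differed from those above by at most 2 members in either direction.

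Sex-linked genes differed between the values labelled wildtype and Ret null, although the series describes all embryos as male. Xist stood at 0.136 FPKM in wildtype and 31.8 FPKM in Ret null (7.88 ± 0.46). The Y-linked genes Kdm5d, Uty and Ddx3y fell by 0.92, 0.99 and 0.78 on the log2 scale, and Eif2s3y, the remaining Y-linked list member that was tested, fell by 0.71 (named after its value was seen). The 4 genes stood at 50.2% to 61.0% of their wildtype values. In this list 4 of 5 tested members fell and 1 rose (adjusted Fisher's exact p = 0.000183). Without genes of the X and Y chromosomes, a setting added after the data were seen, 1868 genes were called.

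**Figure D3:**
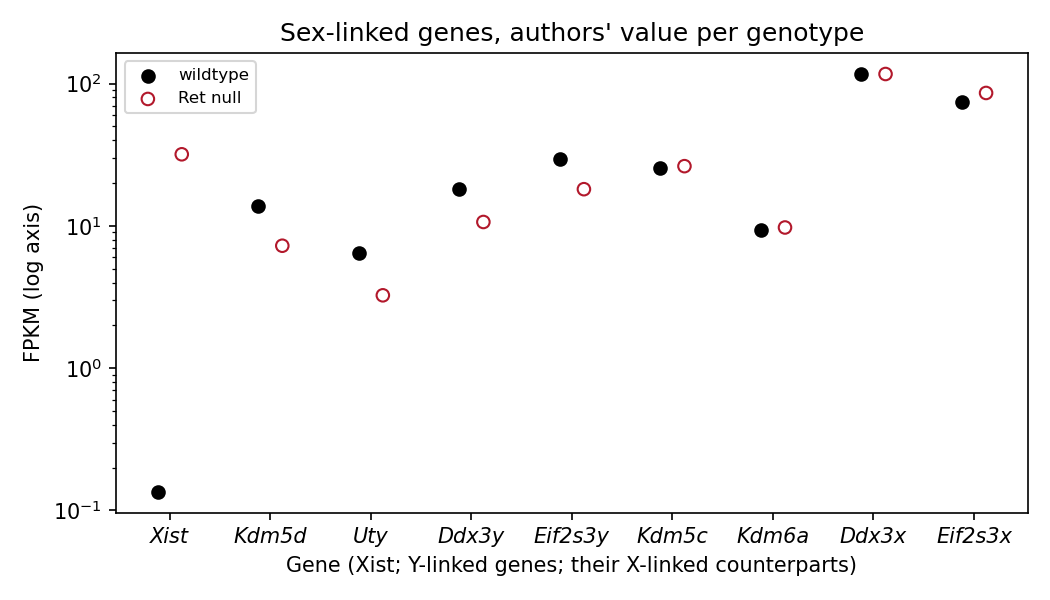
Filled points are the authors' wildtype and open points their Ret null FPKM value (log y axis) for Xist, 4 Y-linked genes and 4 X-linked genes of the same families, with genes on the x axis. Xist rises from 0.136 to 31.8 FPKM while the Y-linked genes lie at 50.2% to 61.0% of wildtype.

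Calls were not more frequent around Ret than elsewhere. Within 10 Mb of Ret, with Ret left out, 13 of 140 tested genes (9.29%) were called, against 14.6% of the other tested genes. The odds ratio was 0.60 (95% interval 0.31 to 1.06, Fisher's exact p = 0.0904, two-sided). By chromosome, calls were more frequent on chromosome 3 (19.2% of 667 genes, adjusted Fisher's exact p = 0.0113) and chromosome Y (4 of 5 genes, 0.0139) and less frequent on chromosome 11 (11.3% of 1093 genes, 0.0113), adjusted over 21 chromosomes. On chromosome 6, which holds Ret, 17.8% of 663 genes were called, Ret included. The odds ratio there was 1.29 and did not pass after adjustment (adjusted Fisher's exact p = 0.0635).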

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

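The tests of dilution, body wall tissue, sex, dissected tissue, age and normalization in this part were chosen only after the results were seen, while the median of crest-restricted markers was fixed before.

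Among the 9802 lines that the authors did not test, 10 were at 1 FPKM or more in Ret null gut and listed at 0 in wildtype, and another 8 showed the reverse. All 18 carry names of microRNAs or small nucleolar RNAs, such as Snord89 at 14.2 FPKM in wildtype, chosen after its value was seen. Libraries of polyadenylated RNA are not made to measure such short RNAs, and some of these lines share the span of a longer locus, so no difference between the genotypes is read from them.

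The first pattern is the 235-fold rise of Xist beside lower Y-linked genes in the Ret null value. Transcription of Xist in male cells with an unchanged number of Y chromosomes would not by itself lower Y-linked genes, and all 4 in the list were lower. These genes are part of the pattern, so their fall describes it and is not independent evidence. RNA of female embryos among the Ret null libraries is a candidate explanation: the median Y-linked value was 55.6% of wildtype, which would leave 44.4% of the Ret null RNA without a Y chromosome, between the 33.3% and 66.7% that 1 or 2 female libraries of 3 would give at equal weight if the wildtype embryos were all male. Over the 4 genes this share was 39.0% to 49.8%, which reaches neither value. Of the X-linked genes of the same families, chosen after their values were seen, Eif2s3x had the highest log2 fold change (0.21 ± 0.17), and none passed. Kdm6a, Kdm5c and Ddx3x stood at 0.06, 0.05 and -0.003. The table has no value per sample, so which libraries carry the signal stays open, as does a genotype effect on these genes.

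The second pattern is the rise of liver, stomach and endoderm genes with the fall of somite, muscle and kidney genes. An offset from the normalization would move all genes alike, so by itself it would not give both directions. The median log2 fold change of hepatic markers (2.28, quartiles 1.17 and 4.23) lay 5.35 above that of somite and skeletal muscle markers. Both lists define the pattern, so their difference describes it and is not independent evidence. The median of all expressed genes was 0.01. In the muscle part the median of somite and skeletal muscle markers was -3.06 without added FPKM (quartiles -3.64 and -1.19). Skeletal muscle genes rise as embryos grow, so older Ret null embryos would not by themselves give this fall. These genes define the pattern and may vary with the tissue dissected, so they do not show embryo age. Different neighbouring tissue taken with the gut is a candidate explanation that stays open (16 of 21 hepatic markers higher, while somite markers were lower). An age difference cannot be told apart from it for the liver and globin part. The 4 adult-type globin lines summed had a log2 fold change of 0.37, and of these Beta-s passed and the other 3 did not, while the embryonic Hbb-bh1 and Hbb-y were lower. An effect of the genotype on these tissues was not tested and may contribute, since all Ret null libraries share it.

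The third pattern is the fall of neural crest and neuronal genes. Dilution of all resident cells by RNA of added tissue would lower endothelial and macrophage markers too, unless that tissue also holds such cells. Their median log2 fold change was -0.10 (quartiles -0.25 and -0.0015), and 27 of 36 lay below 0. The values therefore argue only against strong dilution by tissue without such cells. The 8 markers named beforehand as crest-restricted had a median of -1.59 (quartiles -1.72 and -0.51). Whether other cells in these samples express them was not tested. A lower share of crest derived cells in Ret null gut, the biological explanation that the design gives, is consistent with that median of -1.59, and none of these markers rose, though Ednrb (-0.10) did not pass. Less ganglion and body wall tissue on the Ret null guts is also consistent with the values, since 8 of 10 somite and skeletal muscle markers were lower. Both may act together, since crest cells inside and outside the gut share these markers and no value here separates them.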

How the results depend on the processing

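No paired analysis was possible because the table holds 1 value per genotype. For the same reason leaving out each replicate, the replicate block, quantile normalization, pseudocounts before a test, a count test and other splits of the 6 samples were not run. The numbers of genes called, lower and higher stayed within 1.5 times 1956, 1192 and 764 at q under 0.1, with 1 FPKM or more and with adjustment over expressed genes. Centring leaves the deposited q as it is, so it says nothing about these numbers. With 5 FPKM or more 1249 genes were called and 728 were lower, at q under 0.01 there were 499 higher genes, and with at least 1.5-fold change 1158 were called, 702 lower and 456 higher. Each of these sets is smaller because the rule is stricter. With p from the authors' test statistic as a normal deviate, chosen after seeing the data like the counts without X and Y genes, 607 were called, 376 lower and 231 higher, and 602 of the 607 were among the 1956. The cause was not tested. The log2 fold change of Ret lay between -7.97 and -3.24 over the settings tried. The number of lists with more or fewer calls than elsewhere was 29, and 25 to 28 under the thresholds of 0.1 and 0.01 and the normal p. The odds ratio near Ret ranged from 0.55 to 0.98 with no p under 0.05. Chromosomes with an adjusted p under 0.05 went from 3 to 5 at q under 0.01, when chromosomes 1 and 15 joined, and the cause was not tested. Of 166 named genes 18 no longer passed at q under 0.01, and 1 more passed at q under 0.1. Adding 1 FPKM to both genotypes cannot turn a direction and was used for sizes alone. Of 84 counts of lower or higher list members, 15 moved by more than 1.5 times at q under 0.01, 6 at q under 0.1 and 41 with the normal p. Depth is unknown, and low values carry the largest implied errors.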

Other observations

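The genes and regions in the first paragraph were chosen after their values were seen, except Hbb-bh1, Hba-x and Gata1, which the rule for named genes takes, and the test in the second was fixed before.

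The globin genes did not change together. Beta-s, an adult-type beta globin allele, rose from 82.5 to 338 FPKM (2.03 ± 0.15), while the embryonic Hbb-bh1 fell from 281 to 96.8 FPKM, Hba-x from 1408 to 627 FPKM and Hbb-y from 4532 to 3070 FPKM (q = 0.00468 for Hbb-y in the authors' deposited table). The merged line Hbb-b1,Hbb-b2, whose adult-type genes lie beside Beta-s and can share reads with it, stood at 182 and 201 FPKM and did not pass. Nor did the 2 merged adult-type alpha globin lines Hba-a1,Hba-a2, at 566 and 664 FPKM and at 347 and 321 FPKM in wildtype and Ret null. The red cell regulators Gata1, Klf1 and Epor rose by log2 fold changes of 1.78, 0.92 and 0.87, with q = 0.0113 for Klf1 and q = 0.0133 for Epor in the authors' deposited table. Called genes also lay close together: 29 runs of 10 neighbouring tested genes held 7 or more calls, against a median of 1 and a maximum of 12 in 1000 shuffles of the calls over genes. The runs overlap, so the same calls can count in several runs. The most calls in a single run was 9, and the shuffles also reached 9. On chromosome 4 between 140 and 150 Mb, which holds a cluster of zinc finger genes, 11 of 77 tested genes fell and 9 rose, and on chromosome 17 between 6 and 6.7 Mb, around the Dynlt1 copies, 6 of 9 fell and 1 rose.

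A hypothesis was that DNA of another strain, carried along with the null allele, could place extra calls around Ret. The odds ratio of a call within 10 Mb was 0.60, with a 95% interval of 0.31 to 1.06. That interval lies below the bound of 1.5 set beforehand, which argues against a broad excess of calls at that distance. Over the whole of chromosome 6, Ret included, the odds ratio was 1.29 (95% interval 1.04 to 1.58, adjusted Fisher's exact p = 0.0635). The test within 10 Mb cannot show whether single calls there, or calls elsewhere on chromosome 6 or in the genome, come from such DNA.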
